A study of Caenorhabditis elegans with 8 samples.

How the data were processed

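Each of 8 arrays measured 2 RNA samples of 1 biological replicate, the RNA of cytosolic ribosomes in Cy3 and that of ER-attached ribosomes in Cy5. Per the labels' protocols, 50 ng of RNA were labelled, and there were 4 control and 4 NAC RNAi replicates of strain SS104. The dyes were not swapped. Per the file headers, the arrays were scanned and read with Feature Extraction 11.5.1.1 as 2-colour arrays, all on 1 slide in 1 scan. Spot and background intensities were deposited as scanned, per the file headers, with no normalization. Per the file headers, the deposited processed signals are intensities after spatial and multiplicative detrending, background subtraction and linear plus lowess dye normalization, and the deposited LogRatio is the log10 of processed Cy5 over processed Cy3. The authors also deposited tables of log2 Cy5 over Cy3 made with limma, per the submitters' processing notes, which give no version. Set against the scanner values, these columns had slopes between 0.893 and 0.98 and medians between -0.162 and -0.0381, so that scale and direction were settled, while the normalization within arrays stayed unknown. Between 29.1% and 40.4% of their cells were missing.

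Mean signals and median local backgrounds were corrected with normexp at an offset of 50 and normalized by loess within each array with a span of 0.3 and control spots at weight 0, in limma 3.58.1 under R 4.3.3. Outlier spots were left out, control probes were dropped, saturated spots would have been kept and numbered 0, and spots of a probe were averaged. A probe was tested if it was well above background in either channel on at least 4 of the 8 arrays. Of 57925 probes 55881 carried a WormBase gene ID. By sequence name, or else by gene name, 96.9% of the probes were matched to the gene table. The probe with the highest mean intensity stood for its gene, which gave 16215 genes. Of 4598 genes with several tested probes, the probes were called in opposite directions for 58, 23, 6, 9 and 9 genes in the 5 comparisons. The file headers name an older genome build for the probes, but 95.3% of the gene starts lay within 1 kb of those in the gene table of assembly WBcel235 and 58.4% were identical. Positions were used only to find neighbouring genes and genes of the mitochondrial genome, and none are printed. Data were read with the package data.table (version 1.17.8), and probe sequences were aligned with Biostrings 2.70.1.

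The log2 of ER over cytosol was tested against 0 in control and in NAC RNAi, and the difference between the groups was tested as a contrast, in 1 limma fit over all 8 arrays. For NAC RNAi against control within each fraction, the channel values after loess and Aquantile normalization between arrays were fitted in the same way. Tests were two-sided with Benjamini-Hochberg adjustment, and adjusted p under 0.05 was the threshold. For a gene well above background on none of the 4 arrays of a group, the fold is a bound against the lowest signal well above background on those arrays. Of 38 gene lists fixed before the data were examined, 36 had at least 3 tested genes and were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry beside it. Secretory, cytosolic and mitochondrial lists were pooled into classes, and 4 measures per array were compared with an exact permutation test. The design, the lists, the rule for named genes and most alternatives were chosen before the data were examined.

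The rule for named genes took, per comparison, the 8 largest positive and 8 largest negative values among genes with a symbol, adjusted p under 0.05, mean intensity above the median and all arrays on 1 side (or groups that do not overlap), icd-1 and icd-2, and for each list that passed camera its 3 brightest members and the 2 with the smallest p. It named 628 pairs of gene and comparison. The text prints a part of these, picked after their values were seen, and genes whose call rested on a single array were mostly left out. Counts of kept and lost calls are therefore given over all 628. Of the genes tested, 4379 in the ratio, 4814 in the cytosolic and 6263 in the ER comparison had groups that did not overlap, where chance gives 2.86% of the genes.

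Replicate numbers paired the samples by the rule set beforehand. Arrays of the same number in both groups deviated from their group means together, with correlations over genes of 0.55, 0.27, 0.18 and 0.65 for the ratio, 0.34, 0.19, 0.23 and 0.32 in the cytosolic fraction and 0.32, 0.31, 0.16 and 0.51 in the ER fraction. The rule asked only for values above 0.1. For numbers 2 and 3 of the ratio and number 3 of the ER fraction, an array of another number correlated more (up to 0.29, 0.31 and 0.19). The labels do not say what a number shares, and the number is also the slide row. A fit with the number as a block was run beside the main one.

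Alternatives were no background correction, Agilent's processed signals, median signals, median centring, quantile normalization, no filter and a stricter filter on dim probes, the mean of all probes of a gene, LogRatio (or each channel scaled to its 75th percentile), the authors' tables, channel quantiles without loess, robust eBayes with a trend, each group alone, the replicate block and leaving out each array. Normexp with an offset of 0, centring on the tested genes, LogRatio for the gene lists and the list of mitochondrial genome transcripts were added after the data were seen. The scripts were tested on simulated data with 200 of the 16215 genes changed. In the fit of the ratio difference, 30% of the genes changed by 0.25 log2 were recovered, 84% at 0.5, 92% at 1 and 98% at 2, and 5% of the calls were false. In the fit of the control ratio, 52%, 84%, 98% and 100% were recovered and 8.74% of the calls were false. For NAC RNAi against control in the ER fraction these were 36%, 66%, 94% and 98%, with 7.55% false. Noise was drawn independently for each gene and array, while deviations of the real arrays correlated, and far more genes were called in the data. The shares of false calls therefore do not carry over to the data.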

Results

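RNA from ribosomes of the cytosol was compared with RNA from ribosomes attached to the endoplasmic reticulum (ER) in the nematode Caenorhabditis elegans. Animals of strain SS104, a sterile mutant, were grown in liquid culture at 25 °C and were taken as adults on day 3. RNA interference (RNAi) was done by feeding from the L2/L3 larval stage, with an empty vector in the control group and with bacteria against the nascent polypeptide-associated complex (NAC) in the NAC RNAi group. NAC binds ribosomes where the new chain leaves the tunnel. Each group held 4 biological replicates, each on 1 array that carried both fractions. Cytosolic RNA was labelled with Cy3 and ER RNA with Cy5 on all 8 arrays, so that a dye effect and a fraction effect cannot be told apart in a ratio of ER over cytosol. Comparisons between the groups set the same dye against itself. The 75th percentile of the background-subtracted cytosolic signal lay between 32.07 and 72.26 over the 8 arrays. That of the ER signal lay between 17.39 and 21.21 in control and between 34.79 and 37.37 in NAC RNAi. Between 38.33% and 44.89% of the spots were well above background in the cytosolic channel, and between 37.05% and 43.84% in the ER channel. All arrays lay on 1 slide, with control in column 2 and NAC RNAi in column 1, so that slide column and group cannot be told apart. The number of arrays limits the precision. Within each fraction, replicates 1 and 2 of a group resembled each other more than 3 or 4, and replicates 3 and 4 likewise. The 4 replicates of a group may therefore not be independent. Values below are log2 with the standard error (SE) of the limma fit and n = 4 arrays per group unless another error is named, and 16215 genes were tested. Folds and counts of 2-fold changes depend on the background correction, and without its offset the called values were between 1.51 and 1.98 times as large at the median in the 5 comparisons.

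The transcripts of both NAC subunits were lower in NAC RNAi, which checked the labels of the arrays. The icd-2 transcript (Y65B4BR.5), which encodes the alpha subunit, lay between 12.39 and 12.58 on the control arrays and between 8.97 and 9.32 on the NAC RNAi arrays in the cytosolic fraction, a log2 change of -3.31 ± 0.08 or 9.94-fold (limma adjusted p = 2e-07). In the ER fraction icd-2 fell 10.3-fold, with a log2 change of -3.36 ± 0.12 (limma adjusted p = 3.53e-06). The icd-1 transcript (C56C10.8), which encodes the beta subunit, changed by -1.27 ± 0.10 in the cytosolic fraction (2.41-fold, limma adjusted p = 7.47e-05) and by -1.51 ± 0.18 in the ER fraction (2.84-fold, limma adjusted p = 4.15e-04).

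The first comparison asked which transcripts sat on ER-attached ribosomes in control animals. Transcripts of secreted and membrane proteins were higher in the ER fraction. The disulfide isomerases pdi-1 and pdi-2, which fold proteins inside the ER, stood at 1.71 ± 0.08 and 1.52 ± 0.08 (3.28- and 2.86-fold, limma adjusted p = 8.21e-07 and 9.54e-07). Among 17 ER lumen chaperones and folding enzymes, 15 were higher and 1 was lower, with a median of 1.21 (camera adjusted p = 8.86e-06, adjusted p = 0.366 with an estimated correlation). Of 81 neuropeptides and insulins, 76 were higher and 0 lower, with flp-16, an FMRFamide-like peptide, at 1.44 ± 0.05 (camera adjusted p = 7.31e-20, adjusted p = 0.366 with an estimated correlation). Of 169 collagens, the proteins of the cuticle, 154 were higher and 4 lower, with col-34 at 1.63 ± 0.07 and col-90 at 1.65 ± 0.07 (camera adjusted p = 3.67e-19, adjusted p = 0.366 with an estimated correlation). Of 48 transthyretin-like secreted proteins, 45 were higher and 0 lower, with ttr-2 at 1.74 ± 0.09 (camera adjusted p = 3.31e-12, adjusted p = 0.366 with an estimated correlation). Of 6 vitellogenins, the yolk proteins, 5 were higher, with vit-6 at 1.38 ± 0.14 (camera adjusted p = 0.0432, adjusted p = 0.488 with an estimated correlation), and this list call ended with LogRatio (limma's camera, adjusted p = 0.0888). Of 138 membrane transporters, 112 were higher and 10 lower (camera adjusted p = 1.37e-11, adjusted p = 0.366 with an estimated correlation). The water channel aqp-7 stood at 2.09 ± 0.10, while the ABC transporters pgp-5 and pgp-6 were on the other side at -1.36 ± 0.06 and -1.43 ± 0.05.

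The largest ER-side values with a symbol included ctb-1, cytochrome b of the mitochondrial genome, at 2.87 ± 0.14 (7.28-fold), the carboxypeptidase ctsa-1.1 at 2.74 ± 0.14 (6.67-fold), cht-3, a chitinase-like protein, at 2.63 ± 0.13, the T2 ribonuclease rnst-2 at 2.55 ± 0.11 and tbh-1, the tyramine hydroxylase of octopamine synthesis, at 2.54 ± 0.13. The value of ctb-1 may come from mitochondria in the membrane fraction, which no array measures apart from the ER. Among 27 genes of the signal recognition particle (SRP) and translocon, which bring ribosomes to the ER, 22 were higher and 4 lower (camera adjusted p = 1.11e-04, adjusted p = 0.366 with an estimated correlation). The translocon-associated trap-1 stood at 1.44 ± 0.09 and the oligosaccharyltransferase subunit ostd-1 at 1.36 ± 0.06. The tail-anchored translocon subunits sec-61.B and sec-61.G were lower in the ER fraction, at -0.38 ± 0.06 and -0.28 ± 0.04 (limma adjusted p = 2.37e-04 and 2.09e-04). With Agilent's processed signals both lay above 0, at 0.08 and 0.17, and with no background correction neither passed (limma adjusted p = 0.063 and 0.75).

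Most lists of cytosolic proteins were lower in the ER fraction of control animals. Of 37 glutathione S-transferases 13 were lower and 5 higher, and this list did not pass (limma's camera, adjusted p = 0.163). Of 18 glycolytic enzymes 16 were lower and 0 higher, with a median of -0.75, and ipgm-1, the phosphoglycerate mutase, stood at -1.14 ± 0.07 (camera adjusted p = 3.01e-07, adjusted p = 0.366 with an estimated correlation). Of 84 cytosolic ribosomal proteins 59 were lower and 2 higher, with rpl-3 at -0.79 ± 0.05 (camera adjusted p = 6.87e-09, adjusted p = 0.366 with an estimated correlation). Of 33 proteasome subunits 29 were lower and 0 higher, with rpn-3 at -0.49 ± 0.04 (camera adjusted p = 5.94e-07, adjusted p = 0.375 with an estimated correlation). Of 59 cytosolic tRNA synthetases and translation factors 46 were lower and 1 higher, and the isoleucyl-tRNA synthetase iars-1 stood at -0.94 ± 0.05 (camera adjusted p = 5.53e-11, adjusted p = 0.366 with an estimated correlation). The chaperone hsp-90 stood at -1.05 ± 0.06 and the alpha-tubulin tba-1 at -1.32 ± 0.07. Of 26 muscle structural proteins 23 were lower and 0 higher (camera adjusted p = 3.16e-08, adjusted p = 0.366 with an estimated correlation). Among the largest cytosolic-side values of genes with a symbol were those of drh-2, a Dicer-related helicase gene, at -2.32 ± 0.06 (4.98-fold), the MATH-domain genes math-27, math-3 and math-26 at -2.07 ± 0.10, -2.03 ± 0.08 and -2.02 ± 0.05, and the Argonaute genes sago-2 and prg-2 at -1.64 ± 0.11 and -1.58 ± 0.10. The icd-1 ratio was -0.26 ± 0.08 (limma adjusted p = 0.0225), with adjusted p = 0.0832 without control replicate 1, 0.107 without control replicate 2, 0.0562 with no filter on dim probes, 0.488 with no background correction and 0.693 with LogRatio. The icd-2 ratio was -0.21 ± 0.09 and did not pass the test (limma adjusted p = 0.0763). It passed with median centring at -0.62 (limma adjusted p = 8.69e-03), with quantile normalization at -0.34 (0.0158), with centring on the tested genes at -0.37 (0.0218), with control fitted alone (0.028) and without NAC RNAi replicate 1 (0.0389) or 3 (0.0276).

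In control, 5800 genes were higher and 5227 were lower in the ER fraction, and 1124 and 208 of them differed at least 2-fold. Adjusted over the list alone, the counts of the lists above were the same, except for 77 higher neuropeptides and insulins, 60 lower ribosomal proteins and 47 lower translation genes. Of the 36 lists tested, 14 were higher and 14 lower with the preset correlation, and 0 of these calls held with an estimated one. With median centring in place of loess the split of calls moved from 52.6% higher to 18.5% higher (2222 higher and 9820 lower), and the median of all genes moved from 0.00 to -0.25, so that values here are relative to the loess curve of each array.

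The second comparison asked the same of NAC RNAi animals. Secretory transcripts lay on the ER side here too. Collagens were among the largest values, with col-98 at 1.75 ± 0.11, col-94 at 1.71 ± 0.13 and col-93 at 1.71 ± 0.13 (3.36-, 3.27- and 3.26-fold). Of 169 collagens 150 were higher and 1 was lower (camera adjusted p = 1.01e-28, adjusted p = 0.529 with an estimated correlation). Of 81 neuropeptides and insulins 65 were higher and 0 lower, with flp-16 at 0.85 ± 0.05 (camera adjusted p = 2.76e-16, adjusted p = 0.529 with an estimated correlation). Of 17 ER lumen chaperones and folding enzymes 15 were higher and 0 lower, with pdi-1 at 1.12 ± 0.08 and pdi-2 at 0.98 ± 0.08 (camera adjusted p = 7.43e-07, adjusted p = 0.529 with an estimated correlation). Of 56 lysosomal and secreted proteases 43 were higher and 3 lower, and cpr-6, a cathepsin B-like protease, stood at 1.11 ± 0.10 (camera adjusted p = 4.05e-09, adjusted p = 0.529 with an estimated correlation). The lectin clec-62 stood at 1.21 ± 0.09 and ctb-1 at 1.98 ± 0.14.

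On the cytosolic side of NAC RNAi animals, 11 of 18 glycolytic enzymes were lower in the ER fraction and 0 were higher, with ipgm-1 at -0.50 ± 0.07 (camera adjusted p = 1.43e-06, adjusted p = 0.529 with an estimated correlation). Of 26 muscle structural proteins 19 were lower and 0 higher, with the actin act-4 at -0.42 ± 0.06 (camera adjusted p = 9.28e-10, adjusted p = 0.529 with an estimated correlation). Among the largest values of genes with a symbol were those of math-26 at -0.58 ± 0.05, oaz-1, the ornithine decarboxylase antizyme, at -0.55 ± 0.11, math-3 at -0.55 ± 0.08 and drh-2 at -0.52 ± 0.06 (limma adjusted p between 1.34e-04 and 3.55e-03). Of 84 cytosolic ribosomal proteins 18 were higher and 13 lower, and the list did not pass (limma's camera, adjusted p = 0.7). The icd-1 ratio was -0.50 ± 0.08 (limma adjusted p = 1.94e-03). In NAC RNAi, 4224 genes were higher and 2331 were lower in the ER fraction, and 309 and 0 of them differed at least 2-fold. Adjusted over the list alone, 155 collagens, 71 neuropeptides and insulins and 47 proteases were higher, 24 muscle genes were lower, 15 ER lumen genes were higher and 1 lower, and the glycolytic count was the same. The split of calls was 64.4% higher with loess, 83% with Agilent's processed signals, 45.9% with quantile normalization, 17.5% with median centring and 47.7% with centring on the tested genes. Without NAC RNAi replicate 1, 2 or 3 the lower genes numbered 1172, 1329 and 1427.

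**Figure D1:**
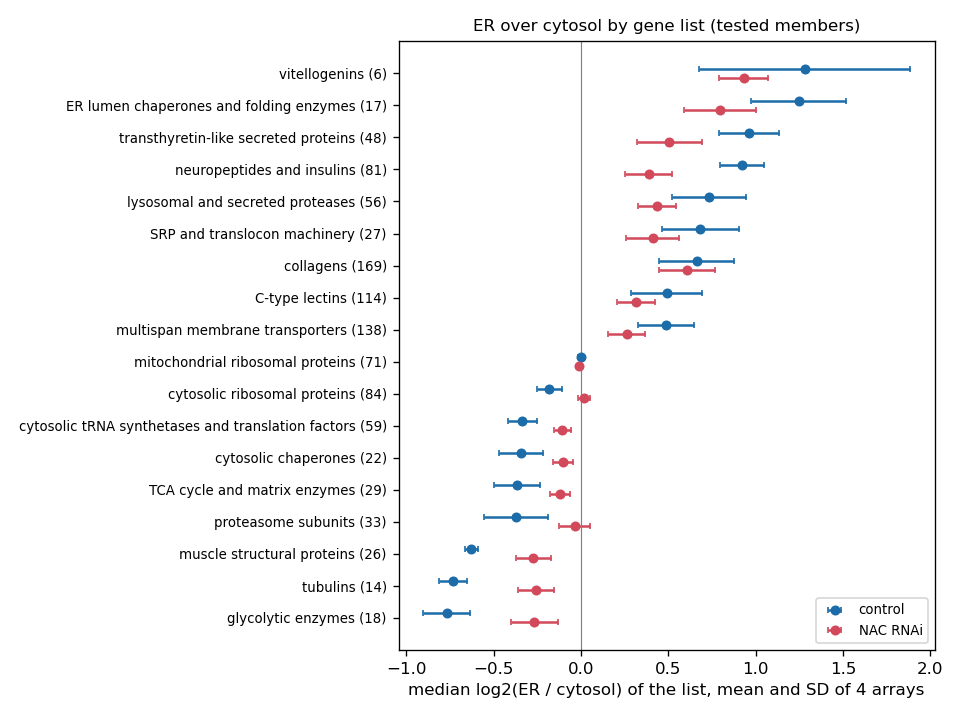
Median log2 ER over cytosol of the tested genes of 18 gene lists, with points for the mean of 4 arrays and bars for the SD, control in blue and NAC RNAi in red. Neuropeptides and insulins stood at 0.92 in control and 0.39 in NAC RNAi, and glycolytic enzymes at -0.77 and -0.27.

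The third comparison asked how NAC RNAi changed the ratio of ER over cytosol. Ratios fell in most lists of secretory transcripts and rose in lists of cytosolic ones, with many members of the larger lists short of the threshold. Of 81 neuropeptides and insulins 69 had a lower ratio and 0 a higher one, with flp-12 at -0.87 ± 0.09 and flp-28 at -0.78 ± 0.09 (camera adjusted p = 9.72e-27, adjusted p = 0.397 with an estimated correlation). Of 48 transthyretin-like proteins 28 fell and 1 rose, with ttr-17 at -0.93 ± 0.10 (camera adjusted p = 1.21e-10, adjusted p = 0.397 with an estimated correlation). Of 17 ER lumen chaperones and folding enzymes 8 fell and 0 rose, with pdi-1 going from 1.71 to 1.12, a change of -0.60 ± 0.11 (camera adjusted p = 1.80e-04, adjusted p = 0.397 with an estimated correlation). Of 27 SRP and translocon genes 11 fell and 2 rose, with trap-1 at -0.66 ± 0.13 and ostd-1 at -0.62 ± 0.09 (camera adjusted p = 5.50e-04, adjusted p = 0.397 with an estimated correlation). Of 138 membrane transporters 54 fell and 6 rose, with aqp-7 at -1.02 ± 0.14, while pgp-6 rose by 1.1 ± 0.08 (camera adjusted p = 7.36e-09, adjusted p = 0.402 with an estimated correlation). Of 169 collagens 18 fell and 2 rose (camera adjusted p = 1.48e-04, adjusted p = 0.634 with an estimated correlation), and the median of the collagens was -0.14 with loess and 0.00 with median centring. Per array their median ratio fell in replicates 1 and 2, from 0.791 to 0.714 and from 0.822 to 0.673. In replicates 3 and 4 it did not fall, at 0.675 and 0.676 and at 0.356 and 0.365. Of 114 C-type lectins 30 fell and 84 did not pass (camera adjusted p = 1.49e-07, adjusted p = 0.402 with an estimated correlation). With fry the lists of collagens (adjusted p = 0.375), lectins (0.0702), proteases (0.0689), transporters (0.0689) and P450 and UDP-glucuronosyltransferase genes (0.0684) did not pass. Of 6 vitellogenins 0 passed the threshold (limma's camera, adjusted p = 0.582), but the replicates disagreed. Their median ratio went from 1.824 to 1.012 and from 1.766 to 0.847 in replicates 1 and 2. It went from 0.899 to 1.084 and from 0.631 to 0.777 in 3 and 4. Among the largest falls of genes with a symbol were those of cht-3 at -1.16 ± 0.18, lipl-1, a lipase-like gene, at -1.12 ± 0.14 and the galectin lec-5 at -1.09 ± 0.20 (limma adjusted p = 3.04e-03, 1.07e-03 and 5.18e-03). With median centring the calls of flp-28 at -0.65 (limma adjusted p = 0.0812), pdi-1 at -0.44 (0.0896) and ostd-1 at -0.44 (0.0965) ended.

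Among cytosolic transcripts, 55 of 84 ribosomal proteins had a higher ratio in NAC RNAi and 0 a lower one, with rpl-5 at 0.44 ± 0.05 (camera adjusted p = 1.5e-18, adjusted p = 0.397 with an estimated correlation). Of 18 glycolytic enzymes 13 rose and 0 fell, with aldo-2, an aldolase, going from -0.84 to -0.19 (camera adjusted p = 1.45e-07, adjusted p = 0.397 with an estimated correlation). Of 59 tRNA synthetases and translation factors 36 rose and 0 fell, with iars-1 at 0.71 ± 0.07 (camera adjusted p = 6.65e-12, adjusted p = 0.397 with an estimated correlation). Of 14 tubulins 11 rose and 0 fell, with tba-1 and tba-2 both at 0.80 ± 0.10 (camera adjusted p = 7.31e-06, adjusted p = 0.397 with an estimated correlation). Of 26 muscle structural proteins 16 rose and 0 fell, with the myosin myo-3 at 0.63 ± 0.09 (camera adjusted p = 1.17e-06, adjusted p = 0.397 with an estimated correlation). Large rises of genes with a symbol were those of drh-2 at 1.79 ± 0.09 (from -2.32 to -0.52), math-27 at 1.56 ± 0.13, math-3 at 1.48 ± 0.11 and math-26 at 1.44 ± 0.08 (limma adjusted p between 9.01e-05 and 3.94e-04). Of 51 nuclear-encoded respiratory chain genes 24 rose and 0 fell (camera adjusted p = 2.98e-08, adjusted p = 0.397 with an estimated correlation). Their median was 0.22 with loess and -0.04 with Agilent's processed signals, and the list did not pass with Agilent's LogRatio (limma's camera, adjusted p = 0.254). In the cytosolic fraction the median of 19 ER unfolded protein response genes was 6.37 ± 0.064 in control and 6.758 ± 0.05 in NAC RNAi (SD, n = 4). In the ER fraction it was 7.42 in both groups. A lower ratio therefore does not mean a lower level of these genes. Their median ratio was 0.18 ± 0.026 in control and 0.11 ± 0.054 in NAC RNAi (SD, n = 4). The arrays overlapped, with control replicate 4 at 0.144 and NAC RNAi replicate 1 at 0.175 for these genes. One of these, the transcription factor transcript xbp-1, rose by 0.42 ± 0.07 (limma adjusted p = 4.02e-03), and this call ended with the processed signals at 0.19 ± 0.12 (limma adjusted p = 0.263), with LogRatio at 0.31 ± 0.12 (0.0663), with an offset of 0 at 0.29 ± 0.12 (0.081) and with median centring, where xbp-1 stood higher at 0.63 with a wider SE of 0.19 (0.117). Median centring also ended the calls of iars-1 at 0.92 (limma adjusted p = 0.0521), myo-3 at 0.83 (0.0746), tba-2 at 0.97 (0.0876), tba-1 at 0.97 (0.0929), aldo-2 at 0.71 (0.149) and rpl-5 at 0.53 (0.167), each with a larger value and a larger SE than with loess.

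In this comparison 2355 genes had a higher ratio in NAC RNAi and 1932 a lower one, and 40 and 34 of them differed at least 2-fold. Adjusted over the list alone, 70 neuropeptides and insulins, 33 transthyretin-like proteins, 9 ER lumen genes, 15 SRP and translocon genes, 65 transporters and 2 collagens fell. By the same adjustment 67 ribosomal proteins, 14 glycolytic enzymes, 40 translation genes, 11 tubulins, 16 muscle genes and 32 respiratory chain genes rose. Of the 36 lists, 16 were higher and 13 lower, and 0 of these calls held with an estimated correlation. The icd-1 ratio changed by -0.24 ± 0.12 (limma adjusted p = 0.171), and with replicate number as a block the adjusted p was 0.0183. The icd-2 ratio changed by -0.05 ± 0.13 (limma adjusted p = 0.821). With the block 3027 genes were higher and 3272 lower. The split of calls was 54.9% higher with loess, 39.1% with no background correction, 32.9% with processed signals, 42.5% with an offset of 0 and 32.3% with median centring, which left 130 higher and 273 lower genes. Without control replicate 1 or 2 the lower genes numbered 1191 and 1088, and without NAC RNAi replicate 2, 3 or 4 they numbered 1274, 1217 and 1188.

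**Figure D2:**
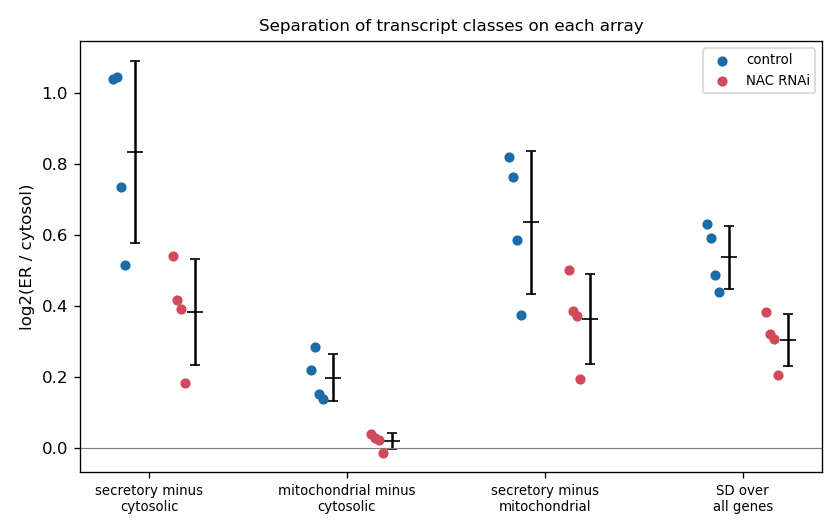
Separation of transcript classes on each array in log2 ER over cytosol, 1 point per array with the mean and SD of 4 arrays beside them, control in blue and NAC RNAi in red. The difference of the secretory and cytosolic medians had a mean of 0.834 in control and 0.383 in NAC RNAi.

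The spacing of whole classes was measured once per array. The median of 762 secretory genes lay above that of 253 cytosolic genes by 0.834 ± 0.257 in control and by 0.383 ± 0.150 in NAC RNAi (SD, n = 4; exact permutation p = 0.0571, 0.0762 after Benjamini-Hochberg adjustment over 4 measures). The median of 179 nuclear-encoded mitochondrial genes lay above the cytosolic one by 0.198 ± 0.0668 and 0.0191 ± 0.0232 (SD, n = 4, exact permutation p = 0.0286, adjusted 0.0571). The lists pooled in this class differed. In control the mitochondrial ribosomal and import lists stood at -0.002 and -0.025. The respiratory chain and TCA lists stood at -0.283 and -0.368, near or below the cytosolic class at -0.277, so that the gap does not hold for mitochondrial transcripts in general. The secretory median lay above the mitochondrial one by 0.636 ± 0.201 and 0.364 ± 0.127 (SD, n = 4; exact permutation p = 0.0857, adjusted 0.0857). The SD of the ratio over all genes was 0.537 ± 0.089 in control and 0.304 ± 0.0738 in NAC RNAi (SD over arrays, n = 4; exact permutation p = 0.0286, adjusted 0.0571). The tests were two-sided over 70 assignments, and none of the 4 measures passed 0.05 after adjustment. The smallest possible p was 0.0286. The mitochondrial minus cytosolic difference and the SD over genes already stood there. They could not pass after adjustment unless another measure also reached this floor. All 4 passed, at an adjusted p of 0.0286, with LogRatio, with an offset of 0 and without control replicate 4. All 4 measures were lower in NAC RNAi in each of the 4 pairs of the same replicate number, and the secretory minus cytosolic difference went from 1.039 to 0.542, from 1.046 to 0.416, from 0.735 to 0.392 and from 0.515 to 0.182. Without regard to pairs, the ranges of the arrays overlapped for both measures that include the secretory class. With numbers paired, a sign-flip test over 4 pairs cannot go below 0.125.

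The fourth comparison set NAC RNAi against control within the cytosolic fraction. Ribosomal protein transcripts fell as a group, with 72 of 84 lower, 0 higher, a median of -0.42 and rps-2 at -0.63 ± 0.04 (camera adjusted p = 1.73e-35, adjusted p = 0.402 with an estimated correlation). Of 59 tRNA synthetases and translation factors 22 fell and 5 rose, with the elongation factor eef-1B.1 at -0.55 ± 0.05 (camera adjusted p = 1.93e-04, adjusted p = 0.522 with an estimated correlation). Of 26 muscle structural proteins 20 rose and 0 fell, with the troponins tnt-2 at 1.17 ± 0.06 and unc-27 at 0.49 ± 0.03 (camera adjusted p = 5.83e-10, adjusted p = 0.402 with an estimated correlation). Of 169 collagens 70 rose and 6 fell, with col-129 at 2.56 ± 0.44 and col-171 at 1.76 ± 0.36 (camera adjusted p = 1.84e-11, adjusted p = 0.522 with an estimated correlation). The collagen median went from 12.444 to 12.781 and from 12.353 to 12.634 in replicates 1 and 2, and from 11.507 to 12.499 and from 11.235 to 12.48 in 3 and 4, where the control arrays stood lower. Of 10 heat shock inducible chaperones 5 rose and 0 fell, with the small heat shock genes hsp-16.49 at 1.23 ± 0.12 and hsp-16.1 at 0.95 ± 0.15 (camera adjusted p = 0.0165, adjusted p = 0.593 with an estimated correlation). The replicates disagreed in the median of this list, which was 7.158, 7.049, 7.673 and 7.492 on control arrays 1 to 4 and 7.904, 7.867, 7.224 and 7.215 on NAC RNAi arrays 1 to 4, higher in 2 pairs and lower in 2. Of 51 respiratory chain genes 27 rose and 3 fell, with cox-6C at 0.48 ± 0.07 (camera adjusted p = 1.53e-05, adjusted p = 0.402 with an estimated correlation).

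Among cytochrome P450 and UDP-glucuronosyltransferase genes, which act on foreign compounds and lipids, 32 fell, 6 rose and 84 did not pass in the cytosolic fraction, with cyp-34A9 at -1.63 ± 0.06 and cyp-25A5 at -1.28 ± 0.07 (camera adjusted p = 2.56e-05, adjusted p = 0.522 with an estimated correlation). Of 27 SRP and translocon genes 11 rose and 0 fell, with the signal peptidase subunit spcs-2 at 0.59 ± 0.06 (camera adjusted p = 3.52e-03, adjusted p = 0.402 with an estimated correlation), and this call ended with median centring (limma's camera, adjusted p = 0.0549). Of 85 germline markers 46 fell and 1 rose (camera adjusted p = 1.84e-11, adjusted p = 0.522 with an estimated correlation). Their median was 7.119, 7.149, 6.714 and 6.679 on control arrays 1 to 4 and between 6.379 and 6.419 in NAC RNAi, so that control replicates 1 and 2 carried most of the fall. The major sperm protein transcript msp-57 stood at 9.17 ± 1.1 in control and 7.18 ± 0.28 in NAC RNAi (SD, n = 4), a change of -1.99 ± 0.48 (limma adjusted p = 0.0163). Large falls of genes with a symbol, beside icd-2, were those of scl-20, a gene of the secreted SCP-like family, at -4.08 ± 0.10 (17-fold, limma adjusted p = 2e-07), the saposin-like spp-12 at -3.78 ± 0.75 (13.7-fold), dct-8 at -3.70 ± 0.76 (13-fold), and the catechol-O-methyltransferase family genes comt-4 and comt-5 at -2.85 ± 0.10 and -2.82 ± 0.10. Among the largest rises, the lysozymes ilys-5 and lys-4 reached 2.30 ± 0.42 and 1.75 ± 0.20, and asp-1, an aspartyl protease of the intestine, 1.54 ± 0.09 (2.9-fold, limma adjusted p = 2.65e-05). The lysozyme lys-10, not well above background on the control arrays, was at least 2.75-fold higher (limma adjusted p = 8.63e-05).

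In the cytosolic fraction 2214 genes rose and 1844 fell, and 86 and 155 of them changed at least 2-fold. Adjusted over the list alone, 74 ribosomal proteins, 23 translation genes, 34 P450 and UDP-glucuronosyltransferase genes and 56 germline markers fell. By the same adjustment 20 muscle genes, 120 collagens, 5 heat shock chaperones, 32 respiratory chain genes and 12 SRP and translocon genes rose. Of the 36 lists 6 were higher and 7 lower, and 0 held with an estimated correlation. The split of calls was 54.6% higher, 65.3% with Agilent's processed signals and 25.7% with median centring, which left 707 higher genes.

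The fifth comparison set NAC RNAi against control within the ER fraction. Most lists of cytosolic proteins rose there. Of 37 glutathione S-transferases 8 rose and 5 fell, and this list did not pass (limma's camera, adjusted p = 0.752). Of 33 proteasome subunits 32 rose and 0 fell, with rpn-2 at 0.81 ± 0.06 (1.76-fold, camera adjusted p = 2.01e-12, adjusted p = 0.214 with an estimated correlation). Of 18 glycolytic enzymes 13 rose and 0 fell, with ipgm-1 at 1.22 ± 0.08 and pgk-1, the phosphoglycerate kinase, at 1.05 ± 0.05 (camera adjusted p = 9.37e-06, adjusted p = 0.304 with an estimated correlation). Of 26 muscle structural proteins 23 rose and 0 fell, with the troponin T gene mup-2 at 1.75 ± 0.10 (3.36-fold), tnt-2 at 1.65 ± 0.12 and the myosin unc-54 at 1.51 ± 0.16 (camera adjusted p = 4.28e-13, adjusted p = 0.162 with an estimated correlation). Of 14 tubulins 12 rose and 0 fell, with tba-1 at 1.07 ± 0.07 (camera adjusted p = 1.83e-06, adjusted p = 0.162 with an estimated correlation). Of 51 respiratory chain genes 40 rose and 3 fell, with the succinate dehydrogenase subunit sdhd-1 at 0.76 ± 0.04 (camera adjusted p = 1e-11, adjusted p = 0.162 with an estimated correlation). Of 10 heat shock inducible chaperones 5 rose and 1 fell, with hsp-16.49 at 1.27 ± 0.09 and hsp-16.1 at 1.11 ± 0.12 (camera adjusted p = 0.0159, adjusted p = 0.503 with an estimated correlation), and the list median was again higher in replicates 1 and 2 (7.045 to 7.514 and 6.98 to 7.578) and lower in 3 and 4 (7.421 to 7.113 and 7.333 to 7.097). Ribosomal proteins went the other way, with 29 of 84 lower, 2 higher and rpl-31 at -0.48 ± 0.05 (camera adjusted p = 2.94e-06, adjusted p = 0.537 with an estimated correlation), and fry did not pass this list (adjusted p = 0.0678).

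Most lists of secretory transcripts fell in the ER fraction, while collagens as a list did not. Of 169 collagens 15 rose and 4 fell, with a median of 0.35 (camera adjusted p = 8.39e-04, adjusted p = 0.785 with an estimated correlation), and fry did not pass them (adjusted p = 0.305). Control replicates 3 and 4 again stood lower, with collagen medians of 13.404, 13.337, 12.404 and 11.995 on the control arrays and 13.653, 13.556, 13.148 and 12.756 on the NAC RNAi arrays. Of 6 vitellogenins 1 fell and 0 rose, and the list did not pass (limma's camera, adjusted p = 0.379). Of 81 neuropeptides and insulins 66 fell and 2 rose, with the insulin-like ins-19 and ins-10 at -1.75 ± 0.21 and -1.50 ± 0.08 and flp-28 at -0.89 ± 0.08 (camera adjusted p = 4.25e-20, adjusted p = 0.223 with an estimated correlation). Of 138 membrane transporters 64 fell and 7 rose, with the sugar transporter swt-1 at -1.14 ± 0.06 (camera adjusted p = 2.61e-08, adjusted p = 0.436 with an estimated correlation). Among P450 and UDP-glucuronosyltransferase genes 56 fell, 3 rose and 63 did not pass, with cyp-25A2 at -1.54 ± 0.08 and cyp-14A3 at -1.41 ± 0.06 (camera adjusted p = 2.32e-11, adjusted p = 0.29 with an estimated correlation). Of 114 C-type lectins 37 fell and 6 rose, with clec-52 at -1.50 ± 0.11 (camera adjusted p = 8.14e-05, adjusted p = 0.436 with an estimated correlation). Of 17 ER lumen chaperones and folding enzymes 6 fell and 0 rose, with the calnexin cnx-1 at -0.52 ± 0.12 (camera adjusted p = 5.63e-03, adjusted p = 0.537 with an estimated correlation). Of 85 germline markers 39 fell and 1 rose, with msp-57 at -1.60 ± 0.36 (camera adjusted p = 2.88e-06, adjusted p = 0.518 with an estimated correlation), and their median was 6.861, 6.769, 6.545 and 6.558 on control arrays 1 to 4 and between 6.361 and 6.389 in NAC RNAi. Large falls of genes with a symbol, beside icd-2, included scl-20 at -4.93 ± 0.15 (30.6-fold), spp-12 at -3.82 ± 0.69 (14.1-fold), dct-8 at -3.41 ± 0.69 (10.6-fold) and the carboxylesterase gene cest-1.1 at -3.12 ± 0.33 (8.71-fold). The tyrosinase-like tyr-3 changed by -2.51 ± 0.11 and was well above background on 3 of the 4 NAC RNAi arrays. Among the largest rises were col-129 at 2.39 ± 0.53, lys-10 at 2.38 ± 0.30 and the transthyretin-like ttr-14 at 1.52 ± 0.11.

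In the ER fraction 3331 genes rose and 2831 fell, and 158 and 298 of them changed at least 2-fold. Adjusted over the list alone, 32 proteasome subunits, 13 glycolytic enzymes, 24 muscle genes, 12 tubulins, 41 respiratory chain genes and 6 heat shock chaperones rose. By the same adjustment 28 ribosomal proteins, 69 neuropeptides and insulins, 68 transporters, 60 P450 and UDP-glucuronosyltransferase genes, 37 lectins, 6 ER lumen genes and 42 germline markers fell, and of the collagens 1 rose and 3 fell. Of the 36 lists 12 were higher and 12 lower, and 0 held with an estimated correlation. The split of calls was 54.1% higher, and 42% with each channel scaled to its 75th percentile, which gave 4327 lower genes. With median centring it was 63.7% higher, with 1725 lower genes. The ER signal differed between the groups as given above, and it cannot be told apart from the group.

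**Figure D3:**
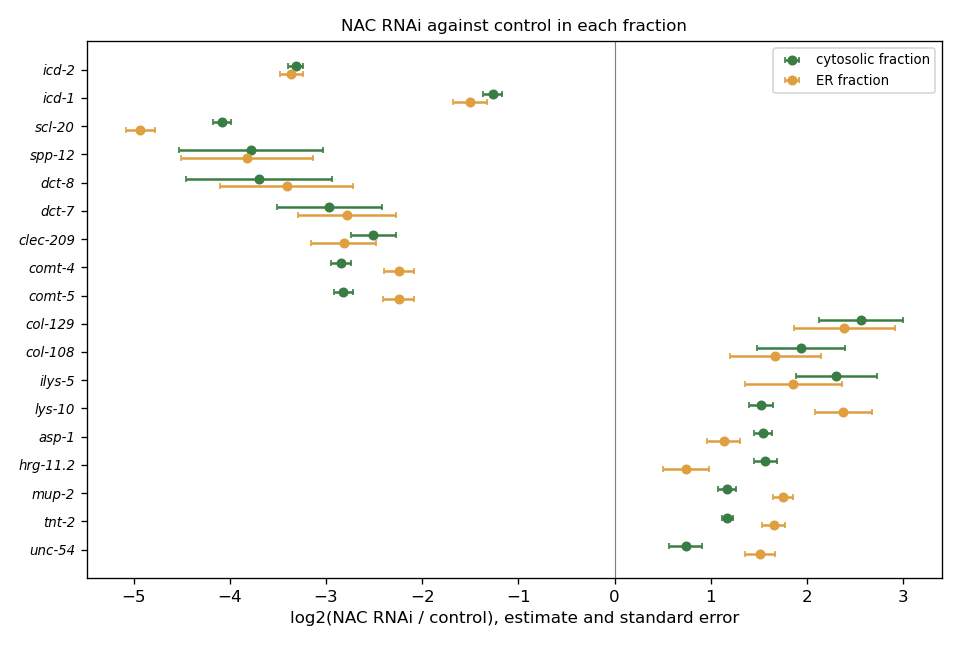
Log2 change of 18 named genes in NAC RNAi against control, estimate and standard error from 4 arrays per group, with the cytosolic fraction in green and the ER fraction in orange. The icd-2 transcript stood at -3.31 in the cytosolic and -3.36 in the ER fraction, and scl-20 at -4.08 and -4.93.

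Changes of the RNAi were set side by side between the fractions. In both fractions 1398 genes rose, where independent lists of these sizes share 454.8, and 952 fell in both, where independent lists share 321.9. Opposite calls numbered 33 genes that rose in the cytosolic and fell in the ER fraction (386.5 for independent lists) and 102 that did the reverse (378.8). Across genes, which are not independent replicates, the changes in the fractions correlated at 0.699. Both fractions of a replicate were measured on the same array. With replicates 1 and 2 for one fraction and 3 and 4 for the other, the correlation was 0.507 and 0.518.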

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

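For the results weighed here, the tests on spike-in probes, on the offset and on single lists under one share were chosen after the result was seen, and the test on a curve and the regroupings of the arrays before.

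For 4287 genes the ratio of ER over cytosol differed between NAC RNAi and control by the test of the difference itself. Of the 35 ways to split the 8 arrays into 4 and 4, 1 gave as many genes, the real one, and the highest other split gave 0 genes. No share smaller than 1 of 35 was possible. Every other split put control and NAC RNAi arrays on the same side, so that a group difference widened the spread there and kept the count low. In the cytosolic fraction the real split gave 4058 genes and the highest other 15, and in the ER fraction 6162 and 13, with 1 of 35 splits as large in each. In both fractions that other split set replicates 1 and 2 of both groups against 3 and 4. Cytosolic control arrays differed with an SD over genes of 0.125 between 1 and 2 and 0.156 between 3 and 4. Across these sets the SD was between 0.249 and 0.292. In NAC RNAi these values were 0.091, 0.095 and between 0.164 and 0.178. What the sets share was not tested. The splits argue against a chance division of the arrays, for the ratio and for both fractions, but they do not part the group from the slide column. The real split is 1 of 8 that part all 4 pairs, and the highest of the other 7 gave 0, 0 and 1 genes. Among these 8 alone the share cannot fall below 12.5%, so that the argument against chance rests on all 35 splits and not on those that keep the pairs.

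The main pattern was a smaller spread of the ratio in NAC RNAi, with an SD over genes of 0.304 against 0.537 in control. This SD also fell with replicate number, which is the slide row, in both groups. It went from 0.63 on replicate 1 to 0.439 on replicate 4 in control, and from 0.383 to 0.205 in NAC RNAi. In each row the NAC RNAi array stood lower, and the cause of the fall along the rows was not tested. A weaker dye response is argued against by 10 spike-in probes, whose SD was 1.7 in both groups (1.66 to 1.75 on the 8 arrays, a ratio of 1 against 0.567 for the genes), and an offset acting on dim probes by the secretory minus cytosolic difference, which in NAC RNAi was 0.456 of that in control with LogRatio and 0.485 over genes well above background on all arrays. One share of cytosolic RNA in the ER fraction, alike for every transcript, was weighed on the collagens. They lay above the value that such a share gives (from the cytosolic class and the neuropeptides) on all 4 NAC RNAi arrays in all 12 settings. The distance was 0.331 ± 0.075 (SD, n = 4) in the analysis of the text and at least 0.093. This argues against one share only with the neuropeptides as the reference. These kept 0.42 of their control median, among the least of the ER-side lists, and the collagens 0.92, so that most secretory lists lay above. The control arrays entered as their mean, so that the SD leaves out their spread (SD 0.213 for the collagens). For other transcripts a share may account for the pattern only in part. Of the other 12 lists, 0 departed by over 2 SD in every setting. However, ER lumen genes lay above on all 4 arrays in all settings (0.247 ± 0.072 SD in the analysis of the text). They did so by over 2 SD in 11 of 12. Proteases lay above by over 2 SD in 10, lectins in 9 and vitellogenins in 6. TCA enzymes departed by over 2 SD in 8, each time below (-0.05 ± 0.023 SD in the analysis of the text). Mitochondrial ribosomal proteins departed by over 2 SD in 7, but not always on the same side. They lay below in the analysis of the text (-0.044 ± 0.008 SD) and above with quantile normalization (0.03 ± 0.009 SD). The last 6 lists departed by over 2 SD in at most 1. The curve test written beforehand (class medians within 0.04 of each other, bound 0.1) was void. Only 13.8% of the secretory genes lay in the range of the cytosolic ones. An effect of NAC depletion on where ribosomes sit, the contrast of the design, and the slide column also stay open, and the former was not tested apart from the group difference itself. The ratio fell as well for the 17 transcripts of the mitochondrial genome, with a median of 2.55 in control and 1.82 in NAC RNAi. Of these 12 were lower and 0 higher. If they came from mitochondria in the membrane fraction, a move of ribosomes off the ER would not directly account for their fall.

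Among 302 groups of 4 arrays of the genes printed or considered for printing, 5 had an array far from the others, where chance gives about 15.1. That expectation does not hold for genes chosen partly because their arrays agreed, and the same arrays recur across genes. The low count therefore says nothing about the quality of the arrays. The control ratio of math-27 was -1.63 on replicate 3 and between -2.27 and -2.19 on the others. That of eef-1A.1, a translation elongation factor, was -1.15 on replicate 4 and between -0.79 and -0.73 on the others. In the ER fraction of control, tyr-3 stood at 8.84 on replicate 3 and between 8.36 and 8.43 on the others, and mdh-2, a malate dehydrogenase, at 10.19 on replicate 3 and between 10.3 and 10.32. In the ER fraction of NAC RNAi, hsp-16.1 stood at 9.43 on replicate 3 and at 9.25 on the others.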

How the results depend on the processing

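Over all 628 pairs of gene and comparison that the rule names, 12616 of 13447 values under the alternatives kept their direction and their side of the threshold, 576 fell short of it, 199 newly passed it and 56 turned direction with a call on at least 1 side. Leaving out 1 array gave 4852 of 5024 kept, 43 newly past, 0 turned and the rest short. Median centring gave 494 of 628 kept, 118 short and 6 turned, and in the ratio difference it ended the calls of pdi-1 (-0.436), ostd-1 (-0.44), flp-28 (-0.648), aldo-2 (0.708), iars-1 (0.917), tba-1 (0.968), tba-2 (0.971), myo-3 (0.832), rpl-5 (0.527) and xbp-1 (0.625), among those printed. Those above 0 were larger than with loess and the others smaller, and the SE was larger for each. The replicate block gave 327 of 359 kept, 3 short and 29 newly past. The cause was not tested for any value below unless it is named.

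Median centring moved the median of all genes to -0.253 in control, -0.158 in NAC RNAi and 0.1 in their difference, and Agilent's processed signals moved it to 0.139 and -0.104 in control and in the difference, LogRatio to -0.101 and the authors' tables to -0.107 in control. With median centring, control had 2222 higher and 9820 lower genes, NAC RNAi 1482 and 6998 and the difference 130 and 273, while 707 genes rose in the cytosolic and 1725 fell in the ER fraction. Genes lower in the ER of NAC RNAi numbered 824 with processed signals, 3810 with quantile normalization and 4970 with centring on the tested genes. Genes with a lower ratio in NAC RNAi numbered 3578 with processed signals, 3113 with quantile normalization, 3199 with LogRatio, 3278 with an offset of 0, 1280 with centring on the tested genes and 3272 with the replicate block. In the ER fraction 4327 genes fell with channels scaled to the 75th percentile. The block moved no other count of genes by more than 1.5 times.

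With 1 array left out, genes higher and lower in the ER of control ranged from 5211 to 5760 and from 4439 to 5142, and those of NAC RNAi from 2910 to 4397 and from 1172 to 2439. Higher and lower ratios ranged from 1723 to 2642 and from 1088 to 2677, genes that rose and fell in the cytosolic fraction from 1567 to 2214 and from 1333 to 1907, and those in the ER fraction from 2730 to 3321 and from 2206 to 2937. The counts that moved by over 1.5 times were the lower genes of NAC RNAi, with 1172, 1329 and 1427 without NAC RNAi replicate 1, 2 or 3, and the lower ratios, with 1191 and 1088 without control replicate 1 or 2 and 1274, 1217 and 1188 without NAC RNAi replicate 2, 3 or 4. Fewer arrays lower the power by construction.

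The class measures passed their test in NAC RNAi minus control, in the order of the text, at -0.76, -0.169, -0.591 and -0.551 with LogRatio and at -0.69, -0.188, -0.502 and -0.441 with an offset of 0 (exact permutation, adjusted p = 0.0286 each). With no background correction 3 passed, at -0.558, -0.163 and -0.316 for the SD (exact permutation, adjusted p = 0.0381). Without control replicate 4 all 4 passed, at -0.557, -0.199, -0.359 and -0.265 (exact permutation, adjusted p = 0.0286). With 1 array left out the 4 measures ranged from -0.557 to -0.38, from -0.199 to -0.151, from -0.359 to -0.21 and from -0.265 to -0.199, and without each of the other 7 arrays none passed.

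With an estimated correlation in camera, 0 lists were higher and 0 lower in each of the 5 comparisons, and all 117 list calls ended. With fry, 6 lists had lower ratios in NAC RNAi and 10 were higher in the cytosolic fraction, and 104 of 117 list calls kept their direction and passed. Median centring kept 113 of 117, LogRatio 68 of 80, and the block 63 of 66, with calls ended for mitochondrial import genes in the cytosolic fraction (adjusted p = 0.0629) and for mitochondrial ribosomal proteins (0.0722) and intestine markers (0.103) in the ER fraction. The ratio change of the histone list turned direction with LogRatio (camera adjusted p = 0.782). Of 936 list medians under other scalings 32 turned sign, and 11 relative to the median of all genes. Single genes that turned in control were icd-1 at 0.034 with processed signals (limma adjusted p = 0.772), sec-61.B at 0.076 (0.337) and sec-61.G at 0.174 (0.0601) with processed signals, and sec-61.G at 0.012 with LogRatio (0.887).

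Signal over background sets a limit. Both channels were well above background on all arrays for 11415 of the 16215 genes. An offset of 50 draws ratios of dim genes toward 0, and with an offset of 0 the called values were 1.98 times as large at the median in control, 1.53 in NAC RNAi, 1.51 in their difference, 1.54 in the cytosolic and 1.76 in the ER fraction. With processed signals these were 2.3, 1.6, 1.6, 1.66 and 1.85, with LogRatio or channel percentiles 2.15, 1.56, 1.59, 1.52 and 1.89, and with the authors' values 2.12 in control and 1.61 in NAC RNAi. With no background correction it was 1.61 in control, and with median centring 0.65 in NAC RNAi.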

Other observations

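Some lists not described above moved as well. In the ER fraction, 60 of 192 nuclear hormone receptors rose in NAC RNAi and 3 fell (camera adjusted p = 5.62e-05, adjusted p = 0.503 with an estimated correlation). Of 29 enzymes of the TCA cycle and matrix 16 rose there and 2 fell, with the aminotransferase got-2.2 at 0.97 ± 0.09 (camera adjusted p = 9.37e-04, adjusted p = 0.162 with an estimated correlation). Of 14 intestine markers 7 rose there and 3 fell, with the intestinal actin act-5 at 1.21 ± 0.06 (camera adjusted p = 0.04, adjusted p = 0.249 with an estimated correlation), and the list did not pass with median centring (limma's camera, adjusted p = 0.0517) or with the replicate block (0.103). Its median rose in replicates 1 and 2 and fell in 3 and 4. Of 57 histones 27 fell and 18 rose in the cytosolic fraction, with his-31 at -1.02 ± 0.07 and his-61 at 0.59 ± 0.03 (camera adjusted p = 6.90e-03, adjusted p = 0.719 with an estimated correlation), and fry did not pass them (adjusted p = 0.0556).

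The patterns below were noticed in the results. The tests on collected mitochondria, on the chance of neighbouring positions and on 45 shared bases were chosen after the result was seen, and those on bright probes and on the same probe sequence before, with the matching of brightness to each transcript added after.

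All 17 transcripts of the mitochondrial genome were higher in the ER fraction of control, with a median of 2.55 against 0.555 for the secretory class, and 15 lay above 0 on all 8 arrays, the others being MTCE.15 and MTCE.18. Their median was 1.82 in NAC RNAi, and 12 had a lower ratio there while 0 had a higher one. A dye bias of bright probes is argued against by nuclear genes within 0.25 log2 of the brightness of each transcript: the distance from their median was 2.54 at the median and over 0.5 for 14 transcripts, the brightest included, and MTCE.15, MTCE.18 and MTCE.28, all dim, were within 0.5. Mitochondria collected with the membranes may carry these transcripts, so that the ER fraction cannot be taken to hold RNA of ER-attached ribosomes only. The 15 transcripts above 0 on all arrays cannot decide how far this goes, since no array measures mitochondria apart from the ER.

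Of the genes at least 4-fold lower in NAC RNAi in both fractions there were 17, icd-2 included, and 8 of them formed 7 pairs within 10 kb, where 10000 random sets of genes had a median of 0 pairs and at most 3 (permutation p = 1e-04, the smallest possible). Identical probes are argued against by the bound of 54 shared bases, written beforehand, which 0% of the pairs reached. The probes of C06H5.12, C06H5.13 and C06H5.14 still shared 50 to 52 of 55 bases, and with a bound of 45 bases, set after the values were seen, their 3 values may be 1 signal counted 3 times. These genes make 3 of the 7 pairs, and the random sets were not redrawn without them, so that the p-value covers all 7 only. The 4 pairs left are still above the highest random count of 3, though 3 neighbouring genes count as 3 pairs. The other pairs, dct-8 with its neighbours F56D6.8 and F56D6.9, and comt-4 with comt-5, shared at most 37 bases, and no biological explanation was tested for them. In the cytosolic fraction dct-8 stood at 12.44, 12.34, 13.26 and 13.27 on the control arrays and at 7.62, 7.61, 10.71 and 10.5 on the NAC RNAi arrays.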
